A study of Mus musculus with 2 samples.

How the data were processed

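H3K36me3 was profiled by chromatin immunoprecipitation and sequencing in 2 biological replicates of liver from mouse embryos of day 14.5, with libraries of 300 to 500 bp, per the labels. Both sexes were pooled in each sample, per the labels. The starting point was 4 deposited peak lists in narrowPeak format on the mm10 build: 1 for each replicate, 1 for both replicates together and 1 of peaks described as replicated. Per the text files deposited beside them, the list of replicate 1 was derived from its own alignments and 2 further files, and that of replicate 2 from its own alignments and 1 further file. The list of replicated peaks was derived from the other 3. The aligner, the peak caller, its settings and the rule that makes a peak replicated are not given in the sources used here.

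Each peak in the deposited lists has a fold, read as the ratio of signal over a background that is not named. Each deposited peak also has a −log10 p and a −log10 q. The lowest −log10 p was about 2 in every list (2.03 in replicate 1 and 2.00 in replicate 2), whereas −log10 q went down to 0.390 and 0.116, so the lists end at a limit on p and none on q. A −log10 q of at least 2 was held by 72.4% of the peaks of replicate 1 and 33.1% of those of replicate 2. The deposited score, a number for display, was not used, nor was the other deposited value, the position of the summit in bp from the start of the peak. Folds and p-values are those of the authors and served to describe, rank and filter peaks within a list and, in 1 test, to count the peaks past the same limit in both lists. The lists hold no read counts, so the depth of the samples is unknown and a gene without peaks may carry a mark too weak for the lists. A sample with fewer reads or a weaker precipitation would give a shorter list, and lengths of lists are therefore not compared as amounts of the mark.

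Genes were taken from GENCODE release M21 on the same build, with the 21 chromosomes X, Y and 1 to 19. Chromosome lengths and assembly gaps came from the matching genome sequence, and no peak and no gene ran past a chromosome end. Where a symbol of a protein-coding gene occurred more than once, the longest gene was kept. The percent covered of a gene is the percent of the bases from its start to its end under peaks of a list. A gene was called marked when this was at least 10% in the list of each replicate, and genes of at least 2 kb were counted. A gene was called marked in 1 replicate when it had at least 10% there and under 1% in the other. Peaks have no strand, so overlapping genes cannot be told apart, and genes with near-identical copies are uncertain.

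The profile along the gene used 20 equal bins over marked genes of at least 10 kb, and the ratio of coverage in the last to that in the first 25% of the gene body was taken from it. The exon to intron ratio used the union of annotated exons of the same genes without the first and last exon. All introns were kept, and bases were summed over genes. The overlap of the replicates was the percent of bases under peaks in both among bases under peaks in either, and the percent of peaks that shared at least 1 bp. Random placements put each peak anywhere outside assembly gaps of its chromosome, 100 times. For the place of peaks in exons, introns and outside genes, all annotated genes were used. The 21 gene lists, 16 given by symbol and 5 by a pattern of symbols, were fixed before the data were examined. So were the thresholds, except for some limits of the tests of explanations at the end. Each list was set against 10000 random lists of as many protein-coding genes matched on deciles of gene length, and the percentile of its median percent covered was given for each replicate. The percentile of the number of marked genes was added after the data were seen, because most genes had no peak. Genes are not replicates, so no p-value across genes was computed, and with 1 group of 2 samples there was no test between groups. Values given with an SD are means of the 2 replicates.

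The named genes were chosen by a rule fixed in advance. It took the 3 highest and 2 lowest genes by mean percent covered in the erythroid, hepatocyte and neuronal lists and the 2 highest and the lowest in the others, with ties by symbol. It also took the 10 genes of at least 10 kb whose lower replicate was highest, the 5 with the largest coverage among genes marked in each replicate alone, the genes at the 5 replicated peaks of highest fold, and Gata1, Klf1, Alas2, Hbb-bs, Hba-a1, Alb, Afp, Ttr, Hnf4a, Apob, Cyp7a1, Cyp3a11, Kit, Xist, Igf2, H19 and Setd2. Members of lists with few measured genes were partly left out.

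The alternatives were peaks with −log10 q of at least 2, the same number of peaks in both lists by −log10 p, peaks up to 1 kb apart joined, the authors' replicated list, the authors' list for both replicates, each replicate alone, coverage of at least 5% or 25%, genes of at least 30 kb for the profile and exons, all exons kept, introns within 500 bp of exons, genes of any length, sharing of at least 50% of both peaks, random shifts within 1 Mb and random lists not matched on length.

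The computations were tested on simulated peaks first. With 200 simulated marked genes among 20327, 100% were called marked and 0 genes were called that overlapped none of them. A single simulated list was used, and its peaks outside these genes lay on chromosome 1 only. On the other chromosomes no such gene could be called, so the check covers the computation and not the error rate of the 10% rule. A ratio of the last to the first 25% of the gene of 2.49 was found as 2.65 and an exon to intron ratio of 1.60 as 1.56 in these 200 genes. The simulated exon to intron ratio kept all exons, whereas the main one leaves out the first and last. The work used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Peaks on sequences outside the chromosomes were left out of all values per gene and chromosome.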

Results

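Trimethylation of histone H3 at lysine 36 (H3K36me3) was mapped by chromatin immunoprecipitation and sequencing in the liver of mouse embryos at day 14.5. H3K36me3 is laid down in the bodies of transcribed genes behind the elongating polymerase, and the liver at this stage is a blood-forming organ as well as the source of hepatocytes. The samples formed 1 group of 2 biological replicates, each with material of both sexes pooled per the labels. There was no second tissue, stage or treatment, so the questions the design allows are where the mark lies, which genes carry it and how far the replicates agree. The peak list of replicate 1 held 106085 peaks over 52.7 Mb, or 1.99% of the chromosomes outside assembly gaps. The list of replicate 2 held 60121 peaks over 30.6 Mb, or 1.16%. The median peak was 325 bp wide in replicate 1 and 335 bp wide in replicate 2. The read depth behind the lists is unknown, so no interval that needs it is given.

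Nearly all genes of the red cell lineage of at least 2 kb were marked, whereas no hepatocyte gene reached the coverage asked for. Of 39 measured erythroid genes, 37 were marked, meaning that peaks covered at least 10% of the gene body in each replicate. With shorter genes included, the count was 37 of 47. The median coverage of the 39 was 66.8% in replicate 1 and 60.4% in replicate 2. None of the 46 measured hepatocyte genes and none of the 35 measured neuronal genes, the list for background, was marked, and their median coverage was 0% in both replicates. Among 10000 random lists of protein-coding genes matched on length, those of the erythroid list's size held 6.75 marked genes on average and at most 16. The median of the erythroid list lay at percentile 100 of the random lists in both replicates.

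The most fully covered erythroid genes were Tfrc, Epb42 and Ermap. Tfrc encodes the transferrin receptor that brings iron into the cell and lies on chromosome 16, 32608920 to 32632794 (mm10 build, here and below). Its body was 92.4% covered in replicate 1 and 88.7% in replicate 2. Epb42, a component of the red cell membrane skeleton (chromosome 2, 121017891 to 121037072), was covered over 86.9% and 84.9% in the same order, which is kept from here on. Ermap, an erythroid membrane protein (chromosome 4, 119175457 to 119190011), was covered over 84.5% and 86.2%. Alas2, the first enzyme of haem synthesis in red cells (chromosome X, 150547375 to 150570638), reached 69.7% and 65.3%, although the annotated body of Apex2 overlaps the whole gene. Of the transcription factors of the lineage, Klf1 (chromosome 8, 84901928 to 84905291) was covered over 47.2% and 45.7%, and Gata1 (chromosome X, 7959260 to 7978071) over 22.5% and 18.4%. The erythroid genes with the lowest coverage were Bcl11a, a repressor of globin genes, at 21.0% and 7.05%, and Bpgm, a red cell metabolic enzyme, at 17.1% and 8.16%. They were the 2 members that missed the threshold, in replicate 2 alone. The adult globin genes Hba-a1 and Hbb-bs, the most familiar erythroid genes, held no peak base in either replicate. They are 0.955 kb and 1.56 kb long, too short for the comparison of lists, and have near-identical neighbours, so that their value of 0 is uncertain.

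Alb and Afp, which encode albumin and alpha-fetoprotein and lie side by side on chromosome 5 (90460897 to 90476602 and 90490737 to 90508907), held no peak in any of the 4 lists. Ttr, the gene of the plasma carrier transthyretin (chromosome 18, 20665280 to 20674321), and Vtn, the gene of vitronectin, were also at 0% in both replicates. The hepatocyte genes with the highest coverage were Serpind1 at 8.30% and 1.65%, Fn1 at 6.40% and 0%, and Hpx at 4.04% and 0%. Serpind1, an inhibitor of blood clotting, lies wholly within Pi4ka on the opposite strand, and peaks have no strand. Apob, the main protein of liver lipoproteins, was covered over 4.00% and 0%, and Hnf4a, a master transcription factor of hepatocytes, over 0.452% and 0%. In replicate 1, 22 of the 46 genes held at least 1 peak, against 2 in replicate 2. In the neuronal list 1 gene held a peak, Syt1, at 0.0419% of its body in replicate 1 and 0% in replicate 2. Camk2a, Celf4, Syn2 and Tubb3 were at 0% in both.

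Random lists of the hepatocyte list's size held 8.02 marked genes on average and at least 1, which placed its count of 0 at percentile 0. The neuronal count of 0 lay at percentile 1.03. The medians themselves did not separate these lists from random ones (hepatocyte percentile 41.6 in replicate 1 and 49.5 in replicate 2), because most protein-coding genes had no peak and most random lists had a median of 0 as well. The hepatocyte and neuronal counts stayed at 0 and the erythroid count between 34 and 39 with −log10 q of at least 2, the same number of peaks, joined peaks, the authors' 2 other lists, each replicate alone, 5% or 25% coverage and genes of any length. The limit on −log10 q, the same number of peaks and 25% coverage can only lower a count. The counts of 0 were thus open to change only under the other alternatives.

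**Figure D1:**
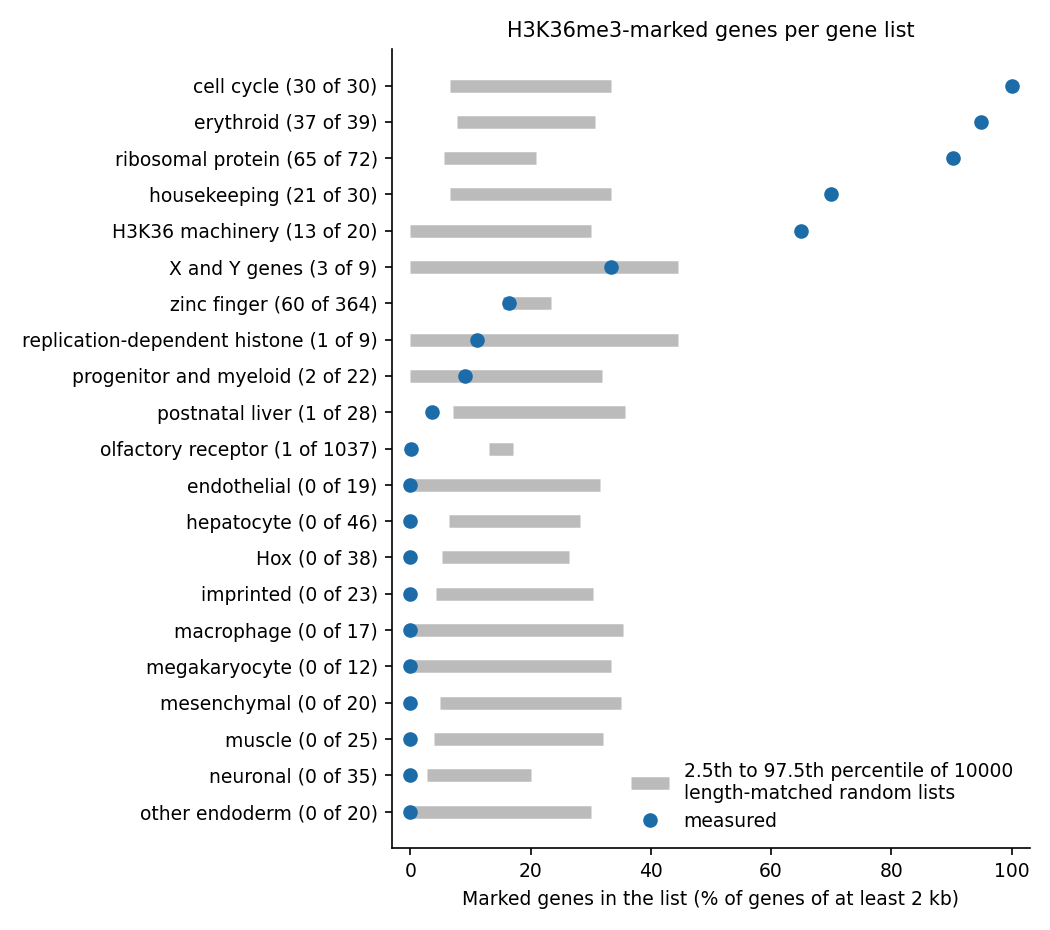
Percent of genes of at least 2 kb that were marked in each gene list (points, with marked and measured genes in parentheses) and the range of 10000 random lists of the same size and gene length (grey bars). Cell cycle, erythroid, ribosomal protein, housekeeping and H3K36 machinery genes lie above the range, and hepatocyte and neuronal genes lie at 0.

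**Figure D2:**
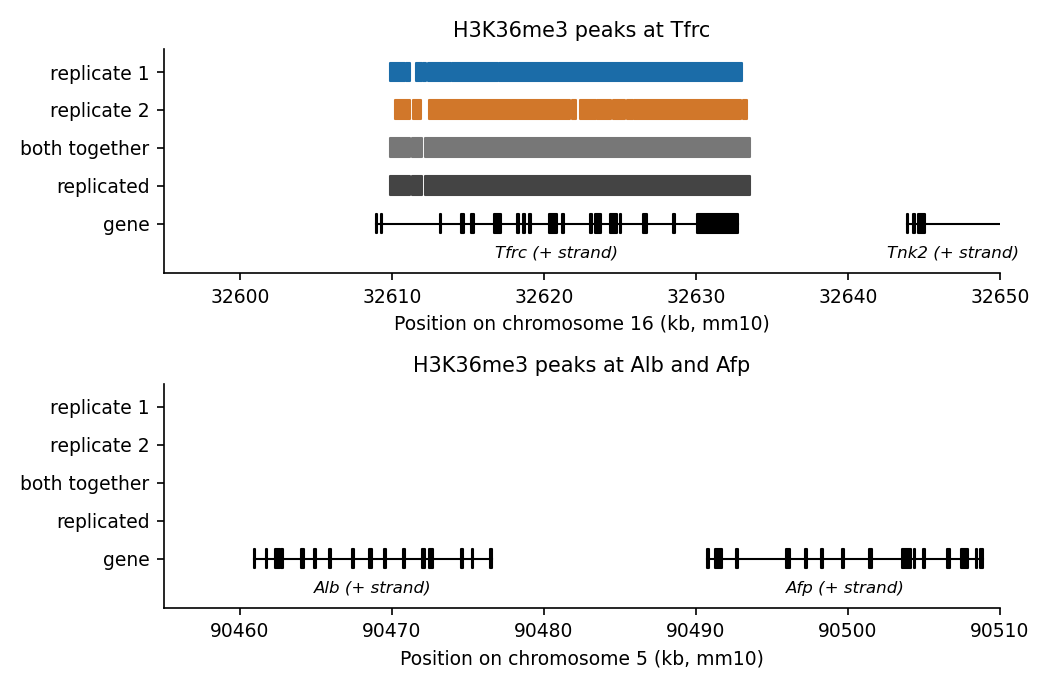
Peaks of the 4 deposited lists (coloured bars) over the annotated exons (black boxes) at Tfrc and at Alb and Afp, in kb on mm10. Peaks cover the body of Tfrc and none of the lists has a peak at Alb or Afp.

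Genes of dividing cells were the most completely marked group. All 30 cell cycle genes were marked, with a median coverage of 81.4% and 76.4%. Top2a, the topoisomerase that untangles replicated chromosomes, reached 95.6% and 94.2%, and Aurka, a mitotic kinase, 91.7% and 93.2%. The lowest member, the condensin gene Ncapg, was at 30.0% and 17.4%. Of the ribosomal protein genes, 65 of 72 were marked, led by Rps3 (84.5% and 77.2%) and Rps15a (85.2% and 72.2%), while Rpl3l, a muscle paralogue, was at 0%. Ribosomal protein genes have many processed copies in the genome, so that their coverage is uncertain where reads were shared. Of the housekeeping genes, 21 of 30 were marked, with medians of 47.4% and 25.8%. Tfrc, which this list shares with the erythroid one, and Eef2, a translation elongation factor (85.2% and 79.4%), were highest, and the X-linked glycolytic gene Pgk1 was lowest at 3.34% and 1.23%. All 3 counts lay at percentile 100 of the length-matched random lists.

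Of 20 genes of the H3K36 methylation machinery, 13 were marked, also at percentile 100. Brpf1, a reader of the mark, was covered over 66.9% and 56.0%, the elongation factor gene Supt6 over 62.2% and 37.7%, and Setd2, the enzyme that deposits H3K36me3 (chromosome 9, 110532597 to 110618633), over 39.3% and 20.2%. Dnmt3b, a DNA methyltransferase recruited by the mark, was lowest at 0.483% and 0%. The count fell to 6 when only peaks with a −log10 q of at least 2 were used.

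No gene was marked among 12 megakaryocyte, 17 macrophage, 19 endothelial and 20 mesenchymal genes, markers of other cells that a fetal liver holds. In replicate 1 a peak was held by 1, 3, 4 and 3 of them. These lists are small: random lists held 1.59, 2.84, 3.02 and 3.58 marked genes on average in the same order, and the counts of 0 lay at percentiles 8.57, 2.10, 1.72 and 0.880, and 0 lay within the central 95% range of random counts for all but the mesenchymal list. With genes of any length, 1 macrophage gene was marked. The highest coverage in these lists was 0.395% and 0% for Fli1 among megakaryocyte genes, 4.06% and 0% for Vcam1 and 1.47% and 0% for Csf1r among macrophage genes, 4.14% and 2.49% for Stab1 and 1.43% and 0% for Egfl7 among endothelial genes, and 3.16% and 0% for Vim and 2.73% and 0% for Cxcl12 among mesenchymal genes. Gp1ba and Vwf, Timd4, Tie1 and Wt1, named for the same lists, were at 0% in both replicates. Of 22 progenitor and myeloid genes, 2 were marked, at percentile 22.2. They were the transcription factor genes Lyl1 (62.6% and 56.7%), which lies within the annotated body of Nfix on the opposite strand, and Ikzf1 (35.8% and 19.1%). Spi1, the master regulator of myeloid cells, was at 0%, and Kit, the stem cell factor receptor, at 0.760% and 0%.

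Genes of the liver after birth were unmarked, with 1 exception in 28. The bile acid transporter gene Slc10a1 (chromosome 12, 80953183 to 80968705) was covered over 37.2% and 34.7%, and its annotated end lies 2675 bp from that of Srsf5, which was itself covered over 59.7% and 56.4%. Bhmt, a methionine cycle enzyme, followed with 0.869% and 0%, and Uox, Cyp7a1, the rate-limiting enzyme of bile acid synthesis, and the drug-metabolising gene Cyp3a11 were at 0%. No gene was marked among 25 muscle genes (Neb at 0.114% and 0%, Acta1 and Ttn at 0%), 20 genes of other endodermal organs (Sftpb at 2.48% and 2.96%, Lct at 2.36% and 0.606%, Sox2 at 0%) or 38 Hox genes (Hoxa1, Hoxa10 and Hoxd9 at 0%). Of 1037 olfactory receptor genes, 1 was marked, against 157 on average in random lists of the same length. It was Olfr419 (chromosome 1, 174248514 to 174252061) at 55.2% and 58.6%, which lies 63 bp beyond the end of the erythroid gene Spta1. Olfr1 and Olfr998 were at 0%.

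None of the 23 imprinted genes was marked. Impact was covered over 20.1% and 2.58% and Gnas over 11.3% and 5.01%, whereas Zim1, Igf2, the fetal growth factor gene, and the noncoding gene H19 were at 0% in both replicates. Of 364 genes named as numbered zinc finger proteins, 60 were marked, against 69.8 on average in random lists (percentile 9.09). Zfp869 (91.7% and 85.2%) and Zfp335 (72.6% and 66.6%) were highest, and Zfp995 was at 0%. The zinc finger count was 117 in replicate 1 alone. The list's median coverage, 2.43% and 0%, lay at percentiles 100 and 50, and 209 of its genes held a peak in replicate 1, against 160 on average in random lists (percentile 100). Of the 9 replication-dependent histone genes long enough to be measured, 1 was marked, Hist3h2a, at 16.8% and 18.5%, which shares its annotated start with Trim17.

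Over all protein-coding genes of at least 2 kb, 3279 of 20327 were marked (16.1%), and 11905 (58.6%) had no peak base in either replicate. The 10 genes of at least 10 kb with the highest coverage in both replicates were Top2a, Slc20a1, Tut7, Aurka, Slc2a1, Ncapd2, Mcm2, Tfrc, Eif4g2 and Abcb10. Each was covered over more than 88% in both. They include the glucose transporter gene Slc2a1 (94.0% and 90.8%), the phosphate transporter gene Slc20a1 (92.1% and 93.6%), the uridylyltransferase gene Tut7 (94.2% and 91.8%), the condensin gene Ncapd2 (90.8% and 90.0%), the replication helicase gene Mcm2 (89.0% and 89.3%), the translation gene Eif4g2 (88.6% and 88.6%) and Abcb10, a mitochondrial transporter needed for haem synthesis (89.1% and 88.4%). The whole of Abcb10 lies within the long gene model Gm20388. The number of marked genes was 1946 with peaks of −log10 q of at least 2, 5193 with the authors' list for both replicates together, 4939 in replicate 1 alone and 1802 when 25% coverage was asked for.

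The 5 replicated peaks with the highest fold, as given by the authors, lay at Fth1, Ppp1r15a, Tfrc, Tpm1 and Car2. The highest, 13.6-fold, covered 2821 bp of chromosome 19 (9983405 to 9986225) at Fth1, the ferritin heavy chain gene, and its neighbour Best1, with 69.9% of its bases in exons. The next, 13.4-fold, was 529 bp long (chromosome 7, 45524324 to 45524852) and lay wholly in coding sequence of Ppp1r15a, a gene of the stress response. A peak of 13.2-fold ran over 21381 bp of Tfrc (chromosome 16, 32612182 to 32633562), with 68.5% of its bases in introns and 12.7% in untranslated regions. Peaks of 12.3-fold lay in Tpm1, a tropomyosin gene (chromosome 9, 67029281 to 67036553, 61.8% intronic), and in Car2, the gene of a carbonic anhydrase of red cells (chromosome 3, 14887064 to 14890314, 77.5% intronic).

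Peak bases lay almost entirely within genes. On average 96.8% ± 0.159 (SD, n = 2) of the bases under peaks fell in annotated genes. In replicate 1, 25.7% lay in exons, 70.9% in introns and 3.34% outside genes, and in replicate 2 the shares were 28.7%, 68.2% and 3.11%. When the peaks of replicate 1 were placed at random in their chromosomes 100 times, 5.24% of bases lay in exons on average and 51.1% outside genes, with no placement below 50.5% outside genes. The random means for replicate 2 were 5.27% and 50.9%. Exons thus held 4.92 times the random share in replicate 1 and 5.45 times in replicate 2, and introns 1.62 and 1.56 times. Shifting each peak by at most 1 Mb, which keeps it in its own neighbourhood, left 39.9% and 39.5% outside genes. Against these shifts the excess was smaller, at 3.05 and 3.28 times for exons and 1.37 and 1.32 times for introns.

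Within genes the mark rose from the start of transcription towards the end. Over 2423 marked genes of at least 10 kb, peaks covered 22.8% of the first 25% of the gene body, 46.2% and 54.9% of the following 2 parts of the same size, and 56.6% of the last 25% in replicate 1. The values for replicate 2 were 13.9%, 31.7%, 39.7% and 42.4%. The ratio of the last to the first 25% was 2.76 ± 0.40 (SD, n = 2). Coverage was higher in the last 25% than in the first 25% in 89.0% of these genes in replicate 1 and in 85.7% in replicate 2. The first of 20 bins, next to the start of transcription, was 3.10% covered in replicate 1.

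**Figure D3:**
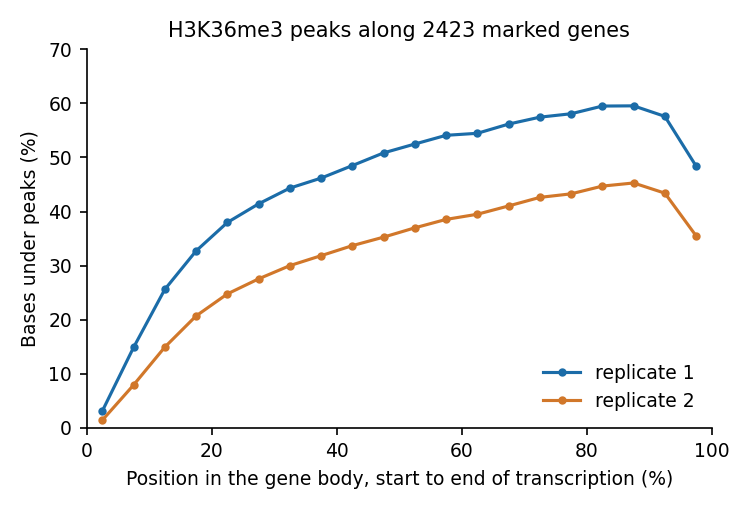
Percent of bases under peaks in 20 equal bins from the start to the end of transcription, averaged over 2423 marked genes of at least 10 kb, for each replicate (lines). Coverage starts at 3.10% in replicate 1 and rises along the gene body in both replicates before it drops in the last bins.

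Exons were covered more than introns. Leaving out the first and last exon, peaks covered 62.1% of exon bases and 39.4% of intron bases of these genes in replicate 1, and 48.0% and 26.5% in replicate 2. The ratio was 1.69 ± 0.166 (SD, n = 2). The introns next to the first and last exon were kept, so this ratio also reflects position along the gene. Against the 500 bp of intron on either side of the exons, which were 55.4% and 40.4% covered, the ratio was 1.15 on average, at 1.12 in replicate 1 and 1.19 in replicate 2.

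Nearly all genes that passed in replicate 2 passed in replicate 1 as well, which held more. At 10% coverage, 4939 genes passed in replicate 1 and 3291 in replicate 2, and 99.6% of the latter also passed in replicate 1. Across the 20327 genes, which are not independent replicates, the percent covered gave a Pearson correlation of 0.950 and a Spearman correlation of 0.892. Bases under peaks in both replicates made up 42.0% of the bases under peaks in either, against 0.864% on average when replicate 2 was placed at random, 0.937% in the highest of 100 placements and 2.08% on average with shifts of at most 1 Mb. Of the peaks of replicate 2, 86.7% shared at least 1 bp with a peak of replicate 1, and 45.1% of the peaks of replicate 1 shared at least 1 bp with a peak of replicate 2. Ranked by −log10 p within the list of replicate 1, sharing went from 93.8% in the strongest 10% of peaks to 18.6% in the weakest 10%.

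In all, 206 genes were marked in replicate 1 with under 1% covered in replicate 2, and 3 genes the other way round. The genes with the largest coverage in replicate 1 alone were Ube2m (48.9%), Tmem81 (40.8%), Tmem185b (38.3%), Exoc8 (35.9%) and Hsbp1 (35.9%), all at 0% in replicate 2 and all shorter than 5 kb. Those of replicate 2 alone were Rpl10 (19.8%), Rab24 (19.5%) and Mrps34 (10.2%), of which Rab24 overlaps Prelid1 and Mrps34 is overlapped over its whole length by other genes. With the same number of peaks taken from both lists the split was 75 in replicate 1 alone and 15 in replicate 2 alone, and with a −log10 q of at least 2 it was 1053 and 0.

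Little of the X chromosome lay under peaks, which is not a measure of the amount of the mark. Peaks covered 0.340% of the X in replicate 1 and 0.131% in replicate 2, against 2.17% and 1.27% of the autosomes. The ratio of X to autosomes was 0.130 ± 0.0372 (SD, n = 2). Of 791 X-linked genes, 24 were marked (3.03%), against 3255 of 19385 autosomal genes (16.8%). Among autosomes, chromosome 11 had the highest coverage (3.96% and 2.35%) and chromosome 14 the lowest (1.32% and 0.696%). The Y chromosome was covered over 0.00732% and 0.00525%, and none of its 151 genes was marked. Of 9 genes of the X and Y chromosomes picked for their roles in dosage and sex, 3 were marked, among them Kdm5c (56.5% and 33.6%) and Ddx3x (52.4% and 21.8%), while Zfy1 was at 0%. The count of 3 lay at percentile 90.8 of random lists and fell to 1 with −log10 q of at least 2 and to 1 at 25% coverage. Xist, the noncoding gene that silences 1 X chromosome in female cells (chromosome X, 103460366 to 103483254), was covered over 15.4% and 0%. The protein-coding gene model Gm26992 overlaps 93.2% of Xist, and the authors' replicated list covered 0.878% of it.

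**Figure D4:**
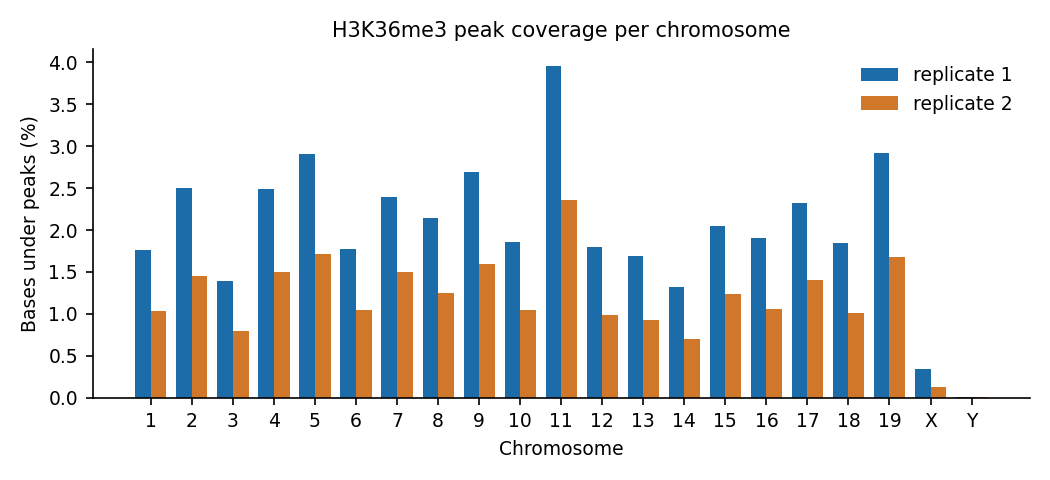
Percent of bases outside assembly gaps under peaks on each chromosome in each replicate (bars). The X chromosome stands at 0.340% in replicate 1 and 0.131% in replicate 2, below every autosome, and the Y chromosome is close to 0.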

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

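Peaks on assembled sequences outside the chromosomes, which no comparison above used, were looked at again because there were more of them than the limit of 3 that a count of 0 allows. There were 20 in the list of replicate 1, 6 in that of replicate 2, 10 in the list for both replicates and 6 in the replicated list. Their highest fold was 5.50 in replicate 1 and 5.48 in replicate 2, and none lay on the mitochondrial sequence. No explanation was tested.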

How the results depend on the processing

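The ratios stayed on the same side of 1 under every alternative run for them, whereas counts and percents have no direction to reverse, and counts in random lists were not computed again. Leaving aside percentiles and values given in passing, 221 of 268 comparisons stayed within a set limit. The limit was the spread between replicates, for counts a change of 1.5 times, and for shared bases and peaks the margin of a 95% binomial interval over peaks. Some comparisons could hardly move. With 1 of 2 replicates left out, a mean of both stays close to or within the spread between them, and a count of 0 cannot rise under stricter limits. The erythroid count lay between 34 and 39, the cell cycle count between 28 and 30 and the ribosomal protein count between 59 and 69, and the hepatocyte, neuronal, megakaryocyte, endothelial, mesenchymal, muscle and Hox counts stayed at 0. The ratio of the last to the first 25% of the gene body lay between 2.40 and 3.05 and that of X to autosomes between 0.104 and 0.137 with −log10 q of at least 2, the same number of peaks and joined peaks, the only alternatives run for it. Stricter limits on p, tried in a test outside these alternatives, took it down to 0.0586 at −log10 p of at least 6. Random lists not matched on length left all 42 percentiles of medians on the same side of the central 95% range. The cause of the changes below was not tested, except where the alternative takes fewer peaks or asks for other coverage.

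With −log10 q of at least 2, marked protein-coding genes fell from 3279 to 1946, zinc finger genes from 60 to 37, H3K36 machinery genes from 13 to 6, X and Y genes from 3 to 1, progenitor and myeloid genes from 2 to 1 and histone genes from 1 to 0. Genes marked in 1 replicate rose from 209 to 1053, shared bases fell from 42.0% to 31.4%, and shared peaks were 24.5% in replicate 1 and 93.5% in replicate 2, with 97.0% of peak bases in genes. With the same number of peaks, genes marked in 1 replicate were 90, shared bases 46.3% and shared peaks 60.5% and 71.4%. With peaks joined they were 399, 50.1%, 39.4% and 85.7%, and 96.9% of peak bases lay in genes. When 50% of both peaks had to be shared, 22.7% and 40.1% were. The authors' replicated list gave 2 imprinted genes, 1 gene of other endodermal organs and 110 zinc finger genes, and their list for both replicates gave 2, 1 and 122, with 5193 marked genes. With 1 replicate left out, marked genes ranged from 3291 to 4939, zinc finger genes from 60 to 117 and imprinted genes from 0 to 2. At 5% coverage there were 91 zinc finger genes, 1 imprinted gene, 629 genes marked in 1 replicate and an exon to intron ratio of 1.93. At 25% these were 21, 0, 24 and 1.45, with 1802 marked genes, 6 of the H3K36 machinery, 1 progenitor and myeloid gene, 1 X and Y gene and 0 histone genes. The exon to intron ratio was 1.46 with all exons and 1.15 against 500 bp of flanking intron. With genes of any length 1 macrophage gene was marked. Depth is unknown, so how far it sets the shorter list cannot be measured.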

Other observations

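The values in this paragraph and the next were chosen after the data were seen. All 8 enzymes of the haem synthesis pathway were marked, from Cpox at 21.4% in replicate 1 and 22.0% in replicate 2 to Ppox at 81.5% and 76.1%. These 8 belong to the erythroid list and were already counted among its 37 marked genes of 39. Alas1, which makes the first step outside red cells, was at 13.2% and 1.88%. Of 10 globin genes, none was marked, and the only one with a peak base was Hbq1a, at 0% in replicate 1 and 20.9% in replicate 2, while Nprl3, the gene beside the alpha globins that holds their enhancers, was covered over 51.2% and 34.0%. Olfr419, the only marked olfactory receptor gene, is the neighbour of the erythroid gene Spta1, which was covered over 73.3% and 68.0%.

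Peaks also ran past the ends of genes. In the 5 kb downstream of 2423 marked genes, 13.9% of the bases outside annotated genes were covered in replicate 1 and 8.37% in replicate 2, against 0.807% and 0.468% in the 5 kb upstream. In the zinc finger list the last exon was covered 3.54 times as much as the rest of the gene in replicate 1 and 4.51 times in replicate 2, against 2.53 and 2.79 times in all other protein-coding genes. Of 7174 genes of other kinds that overlap no protein-coding gene, 32 were marked. The highest were the small nucleolar RNA host gene Snhg1 (91.6% and 79.9%), Malat1 (75.4% and 64.4%), 1110038B12Rik (62.8% and 54.9%) and Mir17hg, the host of a microRNA cluster (83.1% and 54.0%).

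Tests were run for 3 patterns. Those of gene length, of a weak mark, of the gene content of the X chromosome and of weaker peaks in the longer list were chosen after their results were seen, and the last 3 were also changed in what they compare after earlier versions had been run. The design has 1 group and so gives no biological contrast, and the share of erythroid cells was weighed from gene lists alone.

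The first pattern is that erythroid genes were marked and hepatocyte genes were not. Gene length is argued against, because the hepatocyte count lay at percentile 0 of length-matched lists, which held 8.02 marked genes on average. Whether a mark too weak for the peak lists lies on hepatocyte genes stays open. In replicate 1, 47.8% of them held at least 1 peak, against 2.86% of neuronal genes (exact binomial 95% upper limit 14.9%), but in replicate 2 the shares were 4.35% and 0% (limit 10%). The 22 genes with a peak in replicate 1 compare with 19.4 on average in length-matched lists (percentile 78.8), and Alb, Afp and Ttr held none.

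The second pattern is the low coverage of the X chromosome. Gene content is argued against as the whole cause, though by few genes. The 5 lists above all random ones held 8 X-linked genes (4 ribosomal protein genes, 2 housekeeping genes and the marked erythroid genes Alas2 and Gata1). These were 22.0% covered on average, at percentile 0.01 of as many autosomal members drawn from the same lists, whose mean was 50.6%. The lists were picked by their counts in these same data, and gene length was not matched in this test. Coverage of ribosomal protein genes is uncertain. The X mean was also lower in the erythroid list (44.0% against 58.6%) and the housekeeping list (4.21% against 40.6%), each with 2 X-linked genes. Of the 8, 4 were marked, against 160 of 181 autosomal members. As a ratio this gap was smaller than that of 3.03% and 16.8% over all genes, but in percentage points it was wider. Whether gene content gives a part therefore stays open. Repeat content and gene length are argued against too, since autosomal sets matched on both held 124 marked genes on average and at least 84, which put the X count of 24 at percentile 0. Peaks of X-linked genes lay closer to the threshold, as the ratio of X to autosomes fell from 0.130 to 0.0586, or to 0.452 of its value, when −log10 p had to be at least 6; a weaker signal from a single active X in each cell may give this, which was not tested.

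The third pattern is the longer list of replicate 1. Stricter limits did not bring the lists closer. The list of replicate 1 held 1.76 times the peaks of replicate 2 as deposited and 2.11 times with a fold of at least 5. The ratio was 3.86 with −log10 q of at least 2 and 4.48 with −log10 p of at least 6. At milder limits the ratio hardly changed, at 1.77 with a fold of at least 4 and 1.85 with −log10 p of at least 3. These values are the authors' own for each list and depend on a depth that is unknown. A list with more reads can hold more peaks past such limits, so the test cannot decide whether the surplus is one of weaker peaks. In replicate 1, 93.8% of the strongest 10% of peaks by −log10 p were shared, against 18.6% of the weakest 10%. The cause of the surplus stays open. A larger share of erythroid cells in replicate 2 cannot be told apart from stronger peaks in erythroid genes. The erythroid mean in replicate 2 was 6.54 percentage points above that of lists matched on coverage in replicate 1 (percentile 100). It was 2.81 points above lists matched on peak strength too (percentile 99.5). That match was incomplete (mean highest −log10 p 22.6 in erythroid and 20.2 in matched genes). The first comparison also gave cell cycle genes 3.76 points (percentile 99.97) and ribosomal protein genes 3.0 points (percentile 99.96). Housekeeping genes were at 0.901 points (percentile 76.2) and H3K36 machinery genes at −0.677 points (percentile 31.6). An excess was thus not particular to erythroid genes, so the comparison cannot decide on the share of erythroid cells.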
